A study of Mus musculus with 4 samples.

How the data were processed

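Gene expression was measured in whole embryonic gonads of wild-type male mice of the line that the labels call MCH, at embryonic days 12.5, 13.5, 14.5 and 15.5 (E12.5 to E15.5). Per the labels' protocols, gonads were dissected in cold buffered saline and kept frozen in an RNA preservative, total RNA was taken with a silica column kit, and Cy3-labelled cRNA from a low-input linear amplification was hybridised to one-colour Agilent arrays. Each stage had 2 arrays, which the series text calls biological duplicates, so there were 8 arrays in 4 groups.

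Each deposited scanner file held spot intensity on a linear scale, and per the file headers Agilent Feature Extraction had subtracted the background and removed spatial trends within the array, with no scaling between arrays. The submitters' processing notes name Agilent Feature Extraction 9.5, whereas the file headers give 9.1.3.1 for the E12.5 and E13.5 arrays and 9.5.3.1 for the E14.5 and E15.5 arrays. The authors also deposited a table of values with a column per stage, a linear ratio of each probe to a centre over the series. Its columns had medians of 1.14, 1.00, 0.898 and 0.859 for E12.5, E13.5, E14.5 and E15.5. Set against the centred means of the scanner values, the columns correlated across probes at r of 1.000 or just below. The rule by which the table was centred and the level to which its columns were scaled remain unknown, as does how the arrays of a stage were combined. Because it has no separate arrays, the table served only to check directions.

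Every array held 45018 spots, of which 43379 were not control spots, for 41174 probes. Spots of a probe were averaged, and spots that the scanner software marked as outliers were left out unless all spots of the probe were marked. Values were log2 of the processed signal minus the array's 75th percentile of it over all probes that were not controls. Probes were kept if well above background on both arrays of at least 1 stage, which left 28188. Probe names came from the RefSeq accession in the files, matched without versions to gene symbols of the assembly GRCm38.p6. This gave 1 symbol to 22951 probes (55.7%), several to 0 and none to 18223, which kept the identifier of the array's design. With 1 probe per gene name, the one of highest mean, 21986 genes were tested, and 13474 of them had a symbol. Other probes of a gene were compared with the chosen one, and opposite signs or much smaller changes are given where such a gene is named.

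The number of arrays limits the precision, since 2 per stage left 4 residual degrees of freedom, to which the moderated variance added 2.57. Probes well above background ranged from 24810 (60.3%) on E15.5 array 2 to 28724 (69.8%) on E12.5 array 1. Median processed signals ran from 73.3 to 186 and 75th percentiles from 832 to 1833. Saturated probes numbered 32 and 28 on the arrays of slide 2 and 0 on the others. A gene not well above background on either array of its dimmer stage has only a bound there. Its difference is given as "at least N-fold", the mean of the brighter stage over a dim mean in which each array counts as the higher of the probe's own value and the lowest signal among probes well above background. Some genes are not reported here.

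Scanner files tie arrays to 3 slides. Slide 1 held array 1 of E12.5 and E13.5, slide 2 held array 2 of both, and slide 3 held all arrays of E14.5 and E15.5, scanned in a separate session. E13.5 against E12.5 can therefore be compared within slides 1 and 2 and E15.5 against E14.5 within slide 3, whereas E14.5 against E13.5 and E15.5 against E12.5 run across slides.

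All 8 arrays entered 1 linear model with a mean per stage, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The 4 comparisons were each day against the day before and E15.5 against E12.5, and a test over all stages was added. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. These p-values measure only the spread between the duplicates. Values after ± are standard errors of limma for 2 arrays per stage. They rest on 1 moderated variance per gene over all stages, so a gene has the same ± in every comparison. That variance pools duplicates of E12.5 and E13.5, on separate slides, with duplicates of E14.5 and E15.5, on 1 slide. Lists of genes for cell types, germ cell programmes, the cell cycle and signalling pathways, 26 in all, were tested with camera at a preset correlation of 0.01, with adjustment over all lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way without regard to other genes, were run beside it. Within lists, the Benjamini-Hochberg method was also applied to the members alone, and such counts are said to be adjusted over the list alone.

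The comparisons, lists, thresholds, alternatives and the rule for genes to be named were fixed before the data were examined. Per comparison the rule took the 10 higher and the 10 lower called genes of largest change whose arrays did not overlap between stages, up to 4 called members of each list or 2 where none was called, and a set of stage and cell type markers. Names that are only clone or transcript identifiers were left out. The alternatives were normexp background correction, quantile and median scaling, other filters on dim probes, every probe tested, a trended and robust variance, only the arrays compared, blocks for replicate number and slide, a fold threshold, a stricter adjusted p, and leaving out each array. Where an array of a compared stage was left out, 1 array stood for that stage, and the spread came from stages that kept both. Such counts show only how far the calls hang on single arrays. Normexp was to use mean spot signals, but the files used here hold median spot signals, which were used in their place, with an offset of 50. The tests were tested on simulated data with 50 genes changed by each of 4 sizes per comparison. For E13.5 against E12.5, 76% of genes changed 8-fold, 44% of those changed 4-fold and 4% of those changed 2-fold were called among 21986 genes. For E15.5 against E14.5 the shares were 68%, 56% and 8%, and false calls in any comparison numbered 2 to 4. The simulated arrays varied independently, without likeness between arrays of a slide, and few genes changed. These shares and false calls therefore hold for that setting only. Reading and drawing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, with version 1.17.8 of data.table in R.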

Results

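Transcripts of whole male gonads were compared at E12.5, E13.5, E14.5 and E15.5, with 2 one-colour arrays per stage. At these stages the testis cords form, fetal Leydig cells begin to make androgens, and germ cells leave the cell cycle and take up the male fate. A test over all stages includes the step from E13.5 to E14.5, which runs across slides and scan sessions, so it cannot tell slide and stage apart. By that test of limma with Benjamini-Hochberg adjustment, 6829 (31.1%) of 21986 genes tested were called. That number was 4239 without E12.5 array 2, 4333 without E15.5 array 1 and 3594 without E15.5 array 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d, Uty and Zfy2 were well above background on all 8 arrays. Xist, transcribed from the inactive X chromosome of females, was above background on 0 arrays, as were the Y-linked genes Sry and Zfy1. Arrays of a stage correlated across genes at r of 0.977 for E12.5, 0.981 for E13.5, 0.982 for E14.5 and 0.989 for E15.5. Between stages on the same slide, E12.5 and E13.5 gave 0.978 for array 1 and 0.972 for array 2. E14.5 array 1 gave 0.980 with E15.5 array 1 and 0.983 with E15.5 array 2. For E14.5 array 2 these values were 0.986 and 0.972. Duplicates of E12.5 and E14.5 were thus no closer than some arrays of different stages, whereas those of E13.5 and E15.5 were closer than any such pair with their stage. Genes are not independent replicates, so these values describe the arrays only.

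Component 1 of a principal component analysis held 64.2% of the variance and separated the E12.5 and E13.5 arrays on slides 1 and 2 from the E14.5 and E15.5 arrays on slide 3. Within each slide the later stage also lay higher on component 1. E12.5 and E13.5 were at -90 and -48.4 on slide 1 and at -112.4 and -61.5 on slide 2. On slide 3 the E14.5 arrays were at 74.0 and 50.1 and the E15.5 arrays at 81.7 and 106.5. Component 2 held 11.1% of the variance. The authors' table rests on the same arrays, so agreement with it checks only the processing. Called genes that moved the same way in the authors' table were 876 of 876 for E13.5 against E12.5, 2746 of 2746 for E14.5 against E13.5, 144 of 144 for E15.5 against E14.5 and 7702 of 7703 for E15.5 against E12.5. In that order the median change of all genes in that table was -0.18, 0.03, -0.23 and -0.39, and with arrays scaled to their medians it was -0.13 for E15.5 against E14.5 and -0.11 for E15.5 against E12.5. List medians were therefore also taken relative to the median of all genes, and each list called here kept its sign on that basis under every scaling.

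**Figure D1:**
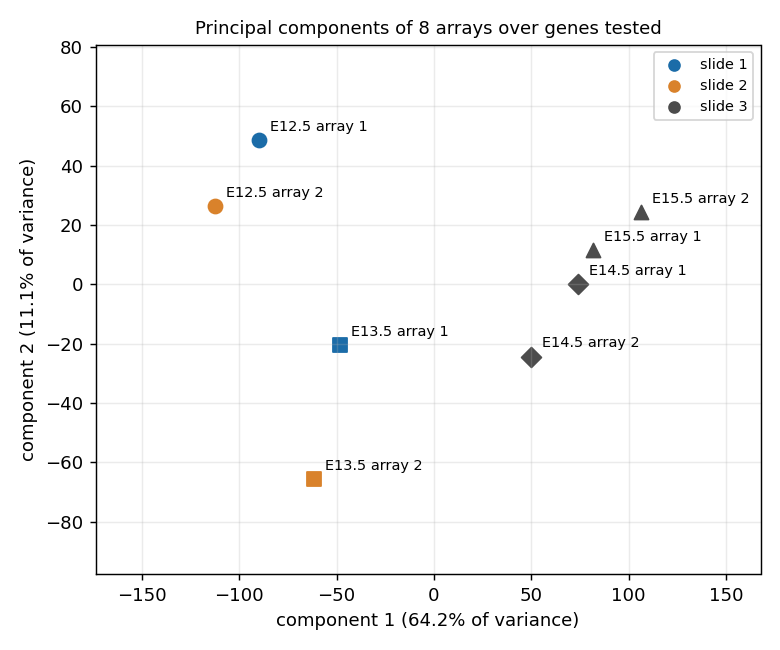
Principal components of the 8 arrays over 21986 genes, with component 1 (64.2% of variance) on the x axis and component 2 (11.1%) on the y axis. Each point is 1 array, its shape gives the stage and its colour the slide, and the slide 3 arrays lie to the right of all others.

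**Figure D2:**
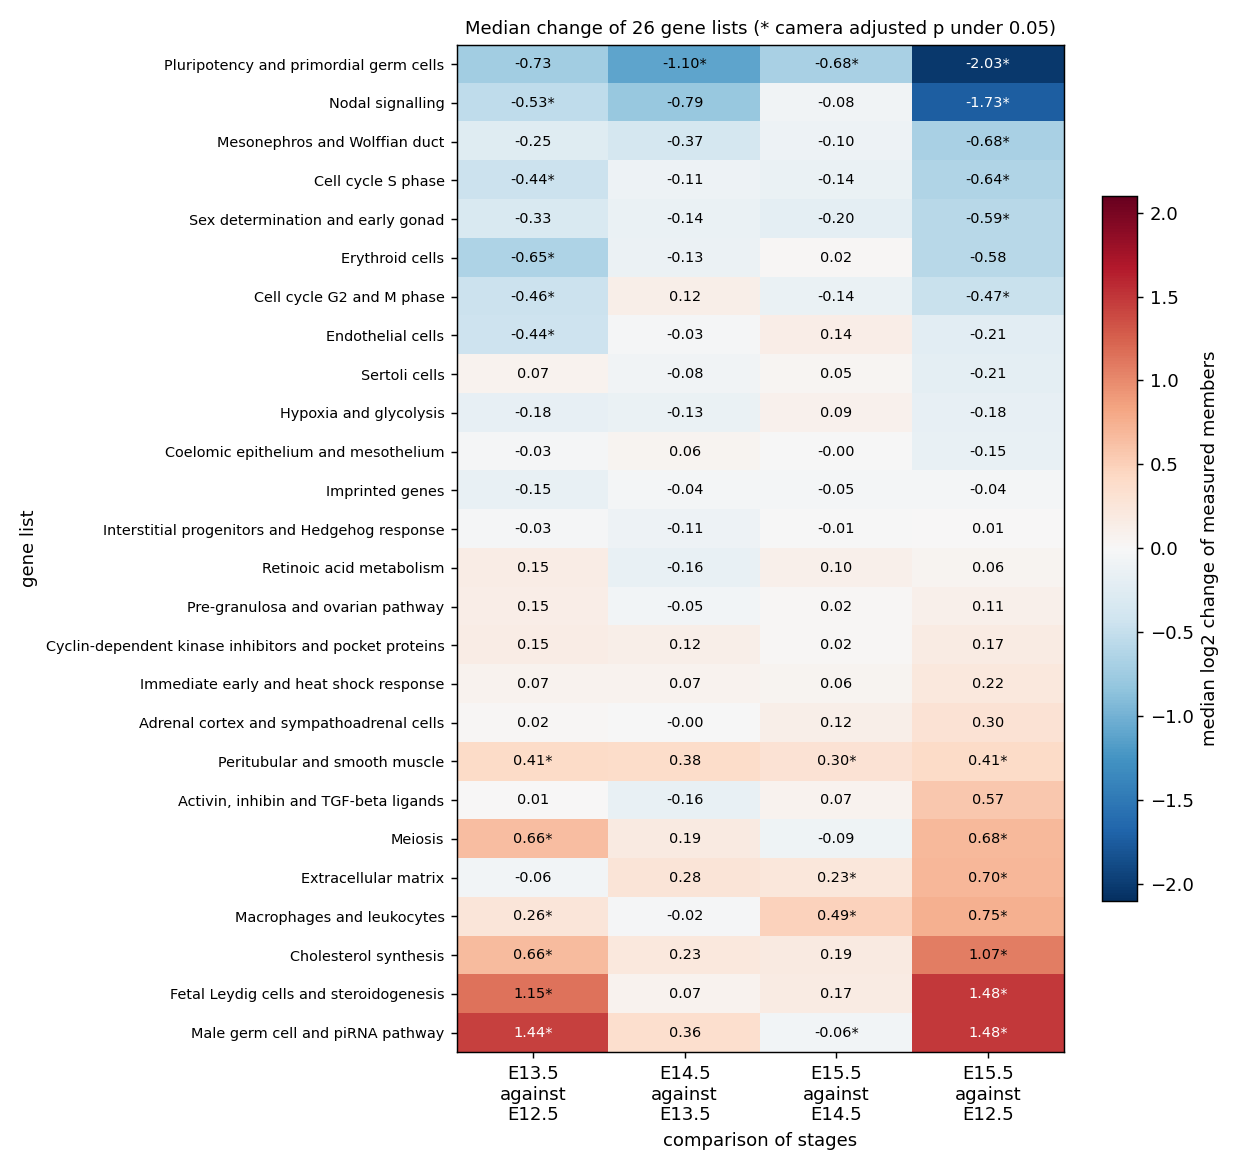
Median log2 change of the measured members of 26 gene lists in 4 comparisons of stages, with red for higher and blue for lower at the later stage. Stars mark camera adjusted p under 0.05, a call that no list kept with an estimated correlation. Medians of lists without a star can change sign with the scaling, and among starred ones that of extracellular matrix for E15.5 against E14.5 was -0.02 in the authors' table.

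Between E12.5 and E13.5, single genes of male germ cells and of steroid-making Leydig cells rose. Dnmt3l, a cofactor of DNA methylation in male germ cells, rose by log2 5.10 ± 0.34 (n = 2 arrays per stage), and Nanos2, an RNA-binding protein of the male germ cell fate, by log2 3.12 ± 0.41. Cyp11a1, which makes pregnenolone from cholesterol, rose by log2 2.81 ± 0.25, and the Leydig cell hormone gene Insl3 by log2 2.62 ± 0.30. Transcripts of the embryonic globin gene Hbb-bh1 changed by log2 -1.99 ± 0.27 and those of Lhx1, a transcription factor gene of the nephric duct, by log2 -2.11 ± 0.18. limma called 876 genes, 590 higher and 286 lower, with Benjamini-Hochberg adjusted p between stages of 0.00155 for Dnmt3l, 0.0133 for Nanos2 and 0.00348 for Cyp11a1. The arrays of the stages did not overlap for 51.3% of genes. Chance gives 33.3% for exchangeable arrays, and 19.3% in a simulation where arrays pair across the stages at the measured correlation.

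Among genes of largest change, the X-linked RNA export factor gene Nxf2 rose by log2 5.93 ± 0.45, the small GTPase gene Rrad by log2 5.88 ± 0.18 and Drc1, a component of motile cilia, by log2 4.85 ± 0.21. Svs5 was at least 24.7-fold and Ctag2 at least 11.7-fold higher at E13.5. The organic anion transporter gene Slco4c1 was at least 3.51-fold and the cadherin family gene Cdhr1 at least 5.66-fold lower. Both changes were positive under normexp background correction, but -0.87 (adjusted p = 0.0631) and -1.12 with its extreme background values replaced. Proc, which encodes protein C, changed by log2 -3.00 ± 0.18, and the X-linked homeobox genes Rhox9 and Rhox6 by log2 -2.79 ± 0.31 and -2.34 ± 0.30.

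Of 21 measured genes of the male germ cell and piRNA pathway, 12 rose, 0 fell and 9 were not called, and 18 were higher and 0 lower when adjusted over the list alone. Their median change was 1.44 (1.44 on slide 1 and 1.61 on slide 2), with camera adjusted p = 2.12e-16, and adjusted p = 0.082 with an estimated correlation. Besides Dnmt3l and Nanos2 they include Henmt1, the methyltransferase of piRNAs, at log2 3.86 ± 0.35 and Morc1 at 3.13 ± 0.21. Meiosis genes had a median of 0.66 (0.72 on slide 1 and 0.51 on slide 2): 5 rose, 2 fell and 14 were not called, and 10 were higher and 3 lower when adjusted over the list alone, with camera adjusted p = 0.000632, and adjusted p = 0.191 with an estimated correlation. Taf7l rose by log2 2.80 ± 0.22, Tex15 by 1.88 ± 0.24 and the synaptonemal complex genes Sycp3 and Sycp1 by 1.81 ± 0.30 and 1.56 ± 0.22. In the same list Sohlh2 changed by log2 -1.27 ± 0.18 and Syce2 by -0.88 ± 0.17, both chosen after their values were seen. Stra8, the gene that opens meiosis in female germ cells, changed by log2 1.49 ± 0.42 and was not called (adjusted p = 0.127).

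Within the list of pluripotency and primordial germ cell genes, 1 rose, 4 fell and 16 were not called of 21, and 2 were higher and 7 lower when adjusted over the list alone, and the list was not called (median -0.73, camera adjusted p = 0.0735, and adjusted p = 0.352 with an estimated correlation). Nanos3 rose by log2 2.098 ± 0.23, whereas Kit, Prdm1 and Tfap2c, which act in early germ cells, changed by log2 -1.59 ± 0.23, -1.25 ± 0.22 and -1.19 ± 0.21. Nodal signalling genes had a median of -0.53 (-0.60 on slide 1 and -0.46 on slide 2), and 0 rose, 1 fell and 10 were not called of 11. In that list 1 was higher and 4 lower when adjusted over the list alone, with camera adjusted p = 0.0393, and adjusted p = 0.191 with an estimated correlation. It lost its call without E12.5 array 1 (adjusted p = 0.174), E13.5 array 2 (0.0655) or either E14.5 array (0.0595), and with probes above background on all arrays (0.0585).

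Fetal Leydig cell and steroidogenesis genes had a median change of 1.15 (0.91 on slide 1 and 1.27 on slide 2). Of 20 genes 11 rose, 0 fell and 9 were not called, 12 were higher and 1 lower when adjusted over the list alone, and the test gave camera adjusted p = 5.59e-11, and adjusted p = 0.135 with an estimated correlation. The angiotensinogen gene Agt rose by log2 2.71 ± 0.25, the cholesterol transport gene Star by 1.76 ± 0.22, and the luteinizing hormone receptor gene Lhcgr was at least 2.68-fold higher. Cholesterol synthesis genes had a median of 0.66 (0.59 on slide 1 and 0.76 on slide 2), and 0 rose, 0 fell and 22 were not called of 22. Adjusted over the list alone 9 were higher, with camera adjusted p = 2.39e-08, and adjusted p = 0.191 with an estimated correlation. Tm7sf2 at log2 1.65 ± 0.36 (adjusted p = 0.0637) and Dhcr7 at 1.08 ± 0.28 (adjusted p = 0.0959) had the largest changes.

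Both cell cycle lists had negative changes in all 24 members of each. For S phase genes 0 rose, 0 fell and 24 were not called, 0 were higher and 0 lower when adjusted over the list alone, and the median was -0.44 (-0.53 on slide 1 and -0.39 on slide 2), with camera adjusted p = 5.92e-06, and adjusted p = 0.191 with an estimated correlation. For genes of G2 and M phase 0 rose, 0 fell and 24 were not called, 0 were higher and 0 lower when adjusted over the list alone, and the median was -0.46 (-0.48 on slide 1 and -0.48 on slide 2), with camera adjusted p = 3.44e-05, and adjusted p = 0.0975 with an estimated correlation. Examples are Ccne1 at log2 -0.86 ± 0.21, Cdc45 at -0.76 ± 0.24, Kif11 at -0.86 ± 0.34 and Top2a at -0.82 ± 0.39, all short of the threshold.

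Erythroid genes had a median of -0.65 (-0.58 on slide 1 and -0.73 on slide 2): 0 rose, 4 fell and 10 were not called, and 2 were higher and 6 lower when adjusted over the list alone. For this list the test gave camera adjusted p = 0.029, and adjusted p = 0.191 with an estimated correlation. The call was lost without E12.5 array 2 (adjusted p = 0.0632), E13.5 array 1 (0.0742) or either E14.5 array (0.0595). It was also lost with probes above background on all arrays (0.0671) and with only the arrays compared (0.0535). Hba-x changed by log2 -1.40 ± 0.24, the erythroid transcription factor gene Klf1 by -1.24 ± 0.21 and the red cell anion exchanger gene Slc4a1 by -1.14 ± 0.21. In the endothelial list 0 rose, 1 fell and 18 were not called, 0 were higher and 2 lower when adjusted over the list alone, and the median was -0.44 (-0.40 on slide 1 and -0.34 on slide 2), with camera adjusted p = 0.00349, and adjusted p = 0.149 with an estimated correlation. The member that fell was the tight junction gene Cldn5, at log2 -0.97 ± 0.18. Peritubular and smooth muscle genes had a median of 0.41 (0.36 on slide 1 and 0.29 on slide 2): 2 rose, 0 fell and 11 were not called, and 2 were higher and 0 lower when adjusted over the list alone, with camera adjusted p = 0.00905, and adjusted p = 0.191 with an estimated correlation. Without E12.5 array 1 (adjusted p = 0.0945) or under normexp (0.24) they were not called. Under normexp with its extreme background values replaced, this list kept its call. The smooth muscle genes Cnn1 and Acta2 rose by log2 1.51 ± 0.21 and 1.39 ± 0.19, though 3 probes of Acta2 ran from 0.20 to 1.39. In the macrophage and leukocyte list 1 rose, 0 fell and 16 were not called, 3 were higher and 0 lower when adjusted over the list alone, and the median was 0.26 (0.10 on slide 1 and 0.37 on slide 2), with camera adjusted p = 0.00413, and adjusted p = 0.352 with an estimated correlation. Without E12.5 array 1 (adjusted p = 0.0945) or E13.5 array 2 (0.278) this list was not called. Its risen member, Coro1a, encodes a leukocyte actin-binding protein and changed by log2 1.88 ± 0.21.

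Sertoli cell genes were not called as a list, with a median of 0.07 that was -0.05 in the authors' table, and 3 rose, 1 fell and 26 were not called of 30. In it 6 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.119, and adjusted p = 0.422 with an estimated correlation. The estrogenic steroid enzyme gene Hsd17b1 rose by log2 1.94 ± 0.18, Clu, a secreted chaperone of Sertoli cells, by 1.51 ± 0.30, and Fgf9, a growth factor of testis formation, changed by -1.37 ± 0.18. Sox9, the transcription factor gene that directs Sertoli cells, changed by log2 -0.85 ± 0.50 (adjusted p = 0.472).

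With slide as a block 981 genes were called, 640 higher and 341 lower, 806 of them among the 876, and the same 11 lists (6 up, 5 down) were called. The count of genes was 579 without E12.5 array 1, 282 without E12.5 array 2, 274 without E13.5 array 1, 188 without E13.5 array 2, and 497 without E15.5 array 1 or without E15.5 array 2. Of the 55 called genes named for this comparison, 18 kept their call whichever array was left out.

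**Figure D3:**
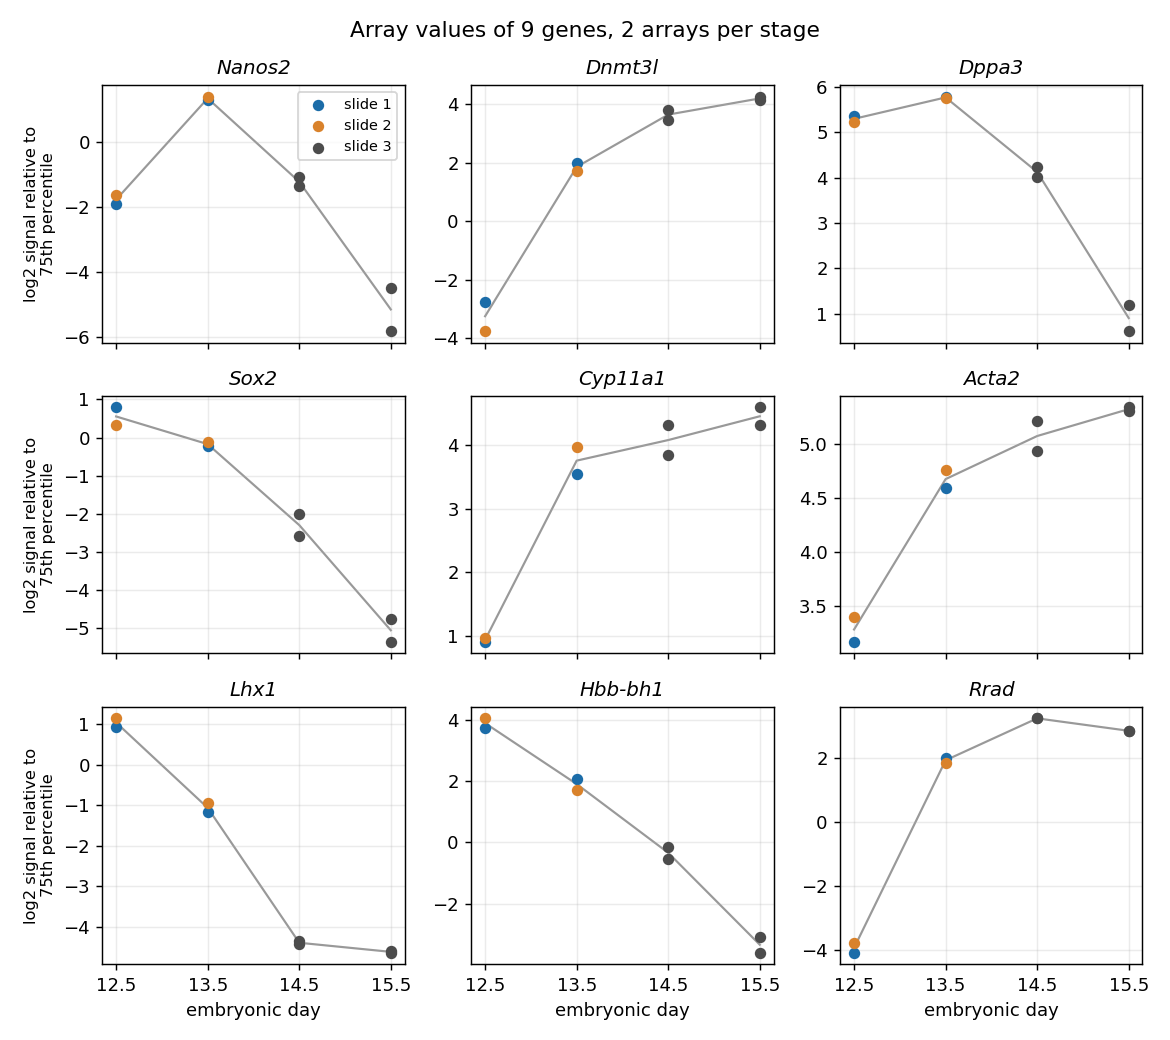
Log2 signal relative to the array's 75th percentile (y axis) by embryonic day (x axis) for 9 genes, with 1 point per array coloured by slide and a grey line through the means of 2 arrays per stage. Nanos2 is highest at E13.5, Dnmt3l, Cyp11a1 and Acta2 are lowest at E12.5, and Dppa3, Sox2, Lhx1 and Hbb-bh1 are lowest at E15.5.

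From E14.5 to E15.5, all on slide 3, single genes of germ cells and of embryonic globins fell. Nanos2 changed by log2 -3.93 ± 0.41 and Nanos3, needed for the survival of early germ cells, by -2.94 ± 0.23 (n = 2 arrays per stage). Dppa3, a maternal and germ cell factor, changed by log2 -3.23 ± 0.23, the pluripotency transcription factor gene Sox2 by -2.77 ± 0.31 and Dppa5a by -2.07 ± 0.23. The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x changed by log2 -3.61 ± 0.38, -3.00 ± 0.27 and -2.55 ± 0.24. limma called 144 genes, 123 higher and 21 lower, with Benjamini-Hochberg adjusted p = 0.0196 for Nanos2, 0.0149 for Dppa3 and 0.023 for Sox2. Arrays did not overlap for 36.4% of genes. Chance gives 33.3% for exchangeable arrays, and 20.8% in the simulation of paired arrays.

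Of the 123 genes called higher, 57 were not above background on either E14.5 array. Ngp, a protein of neutrophil granules, was at least 8.03-fold higher at E15.5 and Lcn2, another granule protein, at least 3.39-fold. The keratin gene Krt26 was at least 4.43-fold, the noradrenaline transporter gene Slc6a2 at least 4.21-fold and the interferon gamma gene Ifng at least 2.61-fold higher. Bounds for Cryba1, a lens crystallin gene, Elf5, Spp2 and Olah were 4.34-fold, 3.32-fold, 2.65-fold and 2.3-fold. The keratin gene Krt33a rose by log2 3.70 ± 0.31. Fam163a and Gtsf1l changed by log2 -2.77 ± 0.27 and -2.66 ± 0.24.

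Pluripotency and primordial germ cell genes had a median change of -0.68, and 0 rose, 4 fell and 17 were not called of 21. In this list 1 was higher and 11 lower when adjusted over the list alone, with camera adjusted p = 6.44e-11, and adjusted p = 0.213 with an estimated correlation. The male germ cell and piRNA list had a median of -0.06: 0 rose, 1 fell and 20 were not called, 0 were higher and 2 lower when adjusted over the list alone, and its call (camera adjusted p = 0.0408, and adjusted p = 0.466 with an estimated correlation) was lost with slide as a block (adjusted p = 0.0728), with quantile scaling (0.22), with probes above background on all arrays (0.0883) and with only the arrays compared (0.0825). It was also lost without E14.5 array 1 (0.46), E15.5 array 1 (0.269) or either E12.5 array (0.0577). Macrophage and leukocyte genes had a median of 0.49: 1 rose, 0 fell and 16 were not called, and 2 were higher and 0 lower when adjusted over the list alone, with camera adjusted p = 2.8e-05, and adjusted p = 0.466 with an estimated correlation. The lysozyme gene Lyz1 rose by log2 1.40 ± 0.20. Extracellular matrix genes had a median of 0.23, which was -0.02 in the authors' table and 0.22 there relative to all genes: 0 rose, 0 fell and 27 were not called, and 0 were higher and 0 lower when adjusted over the list alone. Tested as a group they had camera adjusted p = 0.00798, and adjusted p = 0.466 with an estimated correlation. The call was lost without the filter (adjusted p = 0.115), without E14.5 array 1 (0.529) and without E15.5 array 1 (0.104). The elastin gene Eln was at log2 0.97 ± 0.23 (adjusted p = 0.172) and the laminin gene Lama2 at 0.78 ± 0.29 (adjusted p = 0.433). Peritubular and smooth muscle genes had a median of 0.30: 0 rose, 0 fell and 13 were not called, and 2 were higher and 0 lower when adjusted over the list alone, with camera adjusted p = 0.0246, and adjusted p = 0.466 with an estimated correlation. They too were not called without the filter (adjusted p = 0.121), without E14.5 array 1 (0.516) or without E15.5 array 1 (0.328). Cnn1 was at log2 1.19 ± 0.21 (adjusted p = 0.0809) and Lmod1 at 0.81 ± 0.21 (adjusted p = 0.218). In the erythroid list 0 rose, 3 fell and 11 were not called, and 0 were higher and 3 lower when adjusted over the list alone. It had a median of 0.02 and a mean of -0.57, and camera gave Down (camera adjusted p = 0.123, and adjusted p = 0.466 with an estimated correlation); the median was -0.12 under median scaling and -0.22 in the authors' table.

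Spike-in RNA lay 4.73-fold lower on E14.5 array 1 than on E14.5 array 2, and 2.93-fold lower on E15.5 array 2 than on E15.5 array 1. Without E14.5 array 1, E14.5 array 2 or E15.5 array 2 limma called 0 genes, with 2169, 2126 and 1155 at an unadjusted p under 0.05, and it called 29 without E15.5 array 1, 76 without E12.5 array 1 or without E12.5 array 2, and 78 without E13.5 array 1 or without E13.5 array 2. Fewer lists were called without E14.5 array 1 or E15.5 array 1, and slide as a block gave 226 genes (197 higher, 29 lower, 132 shared). Fry called 2 lists, pluripotency (fry adjusted p = 0.012) and pre-granulosa and ovarian genes (0.0345). Camera had not called the second of these (camera adjusted p = 0.611). The other lists that camera called were not called by fry, with fry adjusted p of 0.0971 to 0.122. Of 23 called genes named for this comparison, 0 kept their call whichever array was left out.

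Between E13.5 and E14.5 single genes of pluripotency, of the nephric duct and of embryonic blood fell, and single genes of the piRNA pathway rose. Lhx1 changed by log2 -3.33 ± 0.18, Sox2 by -2.13 ± 0.31, Gdf3, a growth factor of pluripotent cells, by -2.47 ± 0.22 and Hbb-bh1 by -2.25 ± 0.27 (n = 2 arrays per stage). Dnmt3l rose by log2 1.79 ± 0.34 and the piRNA pathway genes Piwil2 and Tdrd1 by 1.54 ± 0.22 and 1.48 ± 0.33 (0.71 on another probe of Tdrd1), whereas Nanos2 changed by -2.57 ± 0.41. limma called 2746 genes, 1416 higher and 1330 lower, with Benjamini-Hochberg adjusted p = 0.00403 for Lhx1, 0.00505 for Gdf3 and 0.017 for Nanos2. With normexp and extreme backgrounds replaced 1308 were higher and 2627 lower. Only the arrays compared gave 779 genes, no filter 884 and quantile scaling 3096. Arrays did not overlap for 60.02% of genes, against 33.3% by chance for exchangeable arrays. These stages lie on different slides scanned in different sessions, so that slide and stage cannot be told apart here.

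Sly, a Y-linked gene with many near-identical copies that a probe cannot separate, rose by log2 7.01 ± 0.72, with 1 of 2 E13.5 arrays above background. The steroid-inactivating enzyme gene Hsd17b2 was at least 10.9-fold, the forkhead gene Foxa1 at least 11.3-fold, the homeobox gene Gsc at least 7.56-fold and Wnt3a at least 3.86-fold higher. Gsc and Wnt3a were lower under normexp, but at 1.165 and 0.60 (adjusted p = 0.124 for Wnt3a) with extreme backgrounds replaced. Clca1 rose by log2 4.01 ± 0.58 and the troponin gene Tnnc2 by 3.88 ± 0.34. Among lower genes, the synaptotagmin gene Syt10 changed by log2 -7.37 ± 0.80, the splicing factor gene Srrm4 by -3.76 ± 0.28 and the protamine gene Prm1 by -6.28 ± 0.59, though another probe of Prm1 gave 0.58. Otx2, a transcription factor gene of early embryos, was at least 5.54-fold lower.

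The pluripotency and primordial germ cell list was the 1 list called: 0 rose, 9 fell and 12 were not called of 21, and 1 was higher and 11 lower when adjusted over the list alone, with a median of -1.10 and camera adjusted p = 0.0041, and adjusted p = 0.976 with an estimated correlation. Dppa5a changed by log2 -2.28 ± 0.23 and Utf1 by -1.96 ± 0.37. In the Nodal list 1 rose, 4 fell and 6 were not called of 11, and 2 were higher and 5 lower when adjusted over the list alone, with a median of -0.79 and camera adjusted p = 0.179, and adjusted p = 0.976 with an estimated correlation. Lefty1, an inhibitor of Nodal, changed by log2 -4.24 ± 0.55, Foxh1 by -1.31 ± 0.23, and Fgf8 rose by 2.25 ± 0.28. Male germ cell and piRNA genes (3 rose, 2 fell and 16 were not called, and 6 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.143, and adjusted p = 0.976 with an estimated correlation) and mesonephros and Wolffian duct genes (0 rose, 3 fell and 13 were not called, and 0 were higher and 3 lower when adjusted over the list alone, with camera adjusted p = 0.143, and adjusted p = 0.976 with an estimated correlation) were not called as lists. In the second of these Pax2 was at least 2.59-fold lower.

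Meiosis genes moved both ways (4 rose, 2 fell and 15 were not called, and 5 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.683, and adjusted p = 0.976 with an estimated correlation), among them Dmc1, a recombinase, at log2 2.14 ± 0.24 (negative under normexp, but 0.98 with extreme backgrounds replaced), Tex12 at 1.46 ± 0.17, Tex15 at 1.23 ± 0.24 and Sohlh2 at -2.47 ± 0.18. Dazl, a germ cell RNA-binding protein gene chosen after its values were seen, changed by log2 -0.96 ± 0.24 (adjusted p = 0.0473). In the erythroid list 0 rose, 3 fell and 11 were not called, and 0 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.735, and adjusted p = 0.976 with an estimated correlation), with Hbb-y and Hba-x at log2 -1.79 ± 0.38 and -1.79 ± 0.24. Endothelial genes (0 rose, 4 fell and 15 were not called, and 0 were higher and 4 lower when adjusted over the list alone, with camera adjusted p = 0.735, and adjusted p = 0.976 with an estimated correlation) included Kdr at log2 -1.23 ± 0.19, Cldn5 at -1.03 ± 0.18 and Tie1 at -1.005 ± 0.21. Extracellular matrix genes (6 rose, 0 fell and 21 were not called, and 8 were higher and 1 lower when adjusted over the list alone, with camera adjusted p = 0.143, and adjusted p = 0.976 with an estimated correlation) included Eln at log2 1.37 ± 0.23, Fbn1 at 1.18 ± 0.25 and Fbln1 at 1.14 ± 0.23 (0.41 on another probe). Hsd17b1 rose by log2 1.84 ± 0.18 and the steroid dehydrogenase gene Hsd3b6 by 1.21 ± 0.24, and Cyp26b1, which degrades retinoic acid, changed by -1.28 ± 0.17. Probes of Vegfa (log2 1.59 ± 0.32 for the chosen one) ran from -0.36 to 1.59 and those of Stard4 (-0.94 ± 0.23) from -0.94 to 0.86.

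The count of genes was 431 without E13.5 array 1, 219 without E13.5 array 2, 395 without E14.5 array 1 and 1331 without E15.5 array 1 or without E15.5 array 2, and 2 lists were called without E13.5 array 1 or E14.5 array 1. Of 48 called genes named for this comparison, 14 kept their call whichever array was left out.

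Over the whole span, from E12.5 to E15.5, single genes of steroid production and of male germ cells rose, and single genes of embryonic globins, of pluripotency and of the nephric duct fell. Dnmt3l rose by log2 7.44 ± 0.34, Cyp11a1 by 3.51 ± 0.25, Star by 2.48 ± 0.22 and Hsd17b1 by 4.60 ± 0.18 (n = 2 arrays per stage). Hbb-bh1 changed by log2 -7.24 ± 0.27, Sox2 by -5.62 ± 0.31, Lhx1 by -5.66 ± 0.18 and Nanos2 by -3.38 ± 0.41. limma called 7703 genes, 3877 higher and 3826 lower, with Benjamini-Hochberg adjusted p = 9.94e-05 for Dnmt3l, 6.19e-05 for Hbb-bh1 and 4.52e-05 for Lhx1. With normexp and extreme backgrounds replaced 3402 were higher and 5744 lower. Arrays did not overlap for 74.0% of genes, against 33.3% by chance for exchangeable arrays. The stages lie on different slides, and slide and stage cannot be told apart here either.

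Sly was at least 269-fold, the myosin gene Myh2 at least 93-fold, the carotenoid-cleaving enzyme gene Bco2 at least 57.2-fold and Svs5 at least 49.6-fold higher at E15.5. The bound for Myh2 holds for its chosen probe only, since changes on 3 probes of Myh2 ran from log2 4.12 to 7.75. Bounds for Trim61 and the X-linked homeobox gene Esx1 were 33.7-fold and 28.2-fold. Nxf2 rose by log2 8.19 ± 0.45, Ccdc113 by 6.85 ± 0.24 and Rrad by 6.80 ± 0.18. Syt10 changed by log2 -8.10 ± 0.80, Hbb-y by -6.77 ± 0.38 and Hba-x by -5.75 ± 0.24, and Otx2 was at least 13.7-fold lower. Large but uncertain changes were those of Fam110a at log2 -7.85 ± 2.32, Arid5b at -7.11 ± 2.06, Tlx2 at -6.92 ± 2.01 and Pigt at -6.91 ± 2.005. Another probe gave -1.83 for Arid5b and -1.35 for Pigt. For Fam110a the E12.5 arrays gave 2.41 and 8.59, and for Pigt the E14.5 arrays gave 0.76 and 6.67. The Pigt probe was over 4-fold lower on the slide 3 arrays that also read low for spike-in RNA.

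Pluripotency and primordial germ cell genes had a median change of -2.03: 1 rose, 14 fell and 6 were not called of 21, and 1 was higher and 16 lower when adjusted over the list alone, with camera adjusted p = 3.02e-06, and adjusted p = 0.309 with an estimated correlation. Dppa5a changed by log2 -4.92 ± 0.23, Dppa3 by -4.40 ± 0.23 and Pou5f1 by -1.07 ± 0.26, and the member that rose was Dppa4 at 1.16 ± 0.28, chosen after its values were seen. In the Nodal list, with a median of -1.73, 2 rose, 7 fell and 2 were not called, and 2 were higher and 7 lower when adjusted over the list alone, with camera adjusted p = 0.031, and adjusted p = 0.309 with an estimated correlation. The call was lost without E12.5 array 1 (adjusted p = 0.0768) and with probes above background on all arrays (0.104). Lefty1 changed by log2 -5.33 ± 0.55 and Fgf8 by 3.75 ± 0.28. Male germ cell and piRNA genes had a median of 1.48: 13 rose, 2 fell and 6 were not called, and 15 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.000113, and adjusted p = 0.309 with an estimated correlation. Henmt1 rose by log2 5.22 ± 0.35 and Piwil1 by 3.72 ± 0.45. Among meiosis genes, with a median of 0.68, 8 rose, 2 fell and 11 were not called, and 9 were higher and 2 lower when adjusted over the list alone. The list as a whole had camera adjusted p = 0.031, and adjusted p = 0.322 with an estimated correlation. Without E12.5 array 1 (adjusted p = 0.0806) or with a random slide block (0.0665) they were not called. Tex15 rose by log2 3.19 ± 0.24 and Sohlh2 changed by -3.83 ± 0.18, while Sycp1, chosen after its values were seen, stood at -0.16 ± 0.22 (adjusted p = 0.6) and Stra8 at 0.79 ± 0.42 (adjusted p = 0.188). Sycp1 was at 0.0894 without E12.5 array 2.

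Fetal Leydig cell and steroidogenesis genes had a median of 1.48: 12 rose, 2 fell and 6 were not called of 20, and 12 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.000261, and adjusted p = 0.309 with an estimated correlation. Insl3 rose by log2 2.73 ± 0.30 and Lhcgr was at least 10.2-fold higher. Cholesterol synthesis genes had a median of 1.07: 13 rose, 1 fell and 8 were not called, and 14 were higher and 1 lower when adjusted over the list alone, with camera adjusted p = 0.000424, and adjusted p = 0.322 with an estimated correlation. Cyp51 rose by log2 2.20 ± 0.23, Dhcr7 by 2.14 ± 0.28 and Tm7sf2, chosen after its values were seen, by 1.47 ± 0.36. For S phase, 0 rose, 11 fell and 13 were not called of 24 genes, 0 were higher and 11 lower when adjusted over the list alone, and the median was -0.64, with camera adjusted p = 0.00042, and adjusted p = 0.312 with an estimated correlation. For G2 and M phase, 0 rose, 7 fell and 17 were not called, 0 were higher and 7 lower when adjusted over the list alone, and the median was -0.47, with camera adjusted p = 0.0256, and adjusted p = 0.309 with an estimated correlation. The G2 and M phase call was lost with extreme backgrounds replaced under normexp (adjusted p = 0.0776) and with a random slide block (0.0637). Mcm10 changed by log2 -1.48 ± 0.22 and Ube2c by -1.17 ± 0.25.

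Macrophage and leukocyte genes had a median of 0.75: 7 rose, 1 fell and 9 were not called, and 8 were higher and 1 lower when adjusted over the list alone, with camera adjusted p = 0.00413, and adjusted p = 0.412 with an estimated correlation. Lyz1 and Lyz2, lysozyme genes of similar sequence that probes can fail to separate, rose by log2 2.51 ± 0.20 and 1.67 ± 0.23, and Cx3cr1, chosen after its values were seen, changed by -1.32 ± 0.30. Peritubular and smooth muscle genes had a median of 0.41: 5 rose, 0 fell and 8 were not called, and 6 were higher and 0 lower when adjusted over the list alone, with camera adjusted p = 0.0256, and adjusted p = 0.309 with an estimated correlation. Without E12.5 array 1 (adjusted p = 0.0768) or E15.5 array 1 (0.0651) they were not called. Cnn1 rose by log2 3.54 ± 0.21 and Acta2 by 2.04 ± 0.19. Extracellular matrix genes had a median of 0.70: 12 rose, 4 fell and 11 were not called, and 13 were higher and 4 lower when adjusted over the list alone. As a list they had camera adjusted p = 0.031, and adjusted p = 0.412 with an estimated correlation. Their call was lost without E12.5 array 1 (adjusted p = 0.0806) and without E15.5 array 1 (0.0651). Eln rose by log2 3.41 ± 0.23 and the collagen gene Col6a2 by 1.89 ± 0.24. Mesonephros and Wolffian duct genes had a median of -0.68: 1 rose, 5 fell and 10 were not called, and 1 was higher and 5 lower when adjusted over the list alone, with camera adjusted p = 0.0256, and adjusted p = 0.322 with an estimated correlation. Pax2 was at least 2.06-fold lower. Sex determination and early gonad genes had a median of -0.59: 0 rose, 6 fell and 8 were not called, and 1 was higher and 6 lower when adjusted over the list alone, with camera adjusted p = 0.031, and adjusted p = 0.309 with an estimated correlation. This call was lost without E12.5 array 1 (adjusted p = 0.0806), with a random slide block (0.0713) and with extreme backgrounds replaced under normexp (0.0639). In that list the insulin receptor gene Insr and Zfpm2, a cofactor gene of gonad formation, changed by log2 -1.43 ± 0.41 and -1.34 ± 0.22.

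Sertoli cell genes were not called as a list (6 rose, 2 fell and 22 were not called, and 6 were higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.611, and adjusted p = 0.772 with an estimated correlation), and their median of -0.21 and mean of 0.18 differed in sign, the median being 0.03 under quantile scaling. The follicle-stimulating hormone receptor gene Fshr rose by log2 2.33 ± 0.28 and Fgf9 changed by -2.45 ± 0.18. Amh, the hormone that removes the Müllerian ducts, stood at log2 -0.42 ± 0.19 (adjusted p = 0.135) and Sox9 at -0.24 ± 0.50 (adjusted p = 0.732). On this chosen probe Sox9 was at 0.0696 without E12.5 array 1 and 0.0401 without E15.5 array 1. With all arrays, changes on 3 probes of Sox9 were negative, from log2 -0.89 to -0.24. Foxl2, a gene of the ovarian pathway, was at least 2.52-fold lower and the Hedgehog receptor gene Ptch1 changed by log2 -1.79 ± 0.41.

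The count of genes was 4700 without E12.5 array 2, 4965 without E15.5 array 1 and 3492 without E15.5 array 2, and 8 lists in place of 13 were called without E12.5 array 1. Fry called 21. Of 60 called genes named for this comparison, 48 kept their call whichever array was left out.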

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

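The test of exchanged labels and the search for probes that follow the spike-in levels were chosen only after the result was seen.

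Spike-in RNA, added in known amounts at labelling and not used in any comparison, differed between arrays of one stage. Over 5 bright spike-in probes, E14.5 array 1 lay -2.24 (log2) from E14.5 array 2, a 4.73-fold difference, and E15.5 array 2 lay -1.55 from E15.5 array 1, a 2.93-fold difference, relative to each array's 75th percentile. Means of these probes were 4.46, 4.997, 4.51 and 5.20 on the arrays of E12.5 and E13.5, 3.11 and 5.35 at E14.5, and 4.34 and 2.79 at E15.5. Values stood out because spike-in probes should read alike on arrays of one stage. Probes for genes that were over 4-fold lower on both low-spike arrays numbered 22, against 1 that was higher on both and 4 that went opposite ways. With a symbol, these were Abcc10, Cdk5r2, Foxq1, Klf2, Lars2, Pigt, Rusc1 and Tfap2e, all chosen after their values were seen, and 4 of the 22 were called for E15.5 against E12.5. Those with a symbol also differed between E12.5 array 1 and E12.5 array 2. These arrays read 3.242 and 8.461 for Cdk5r2 and 2.959 and 8.708 for Foxq1. They read 5.798 and 9.542 for Rusc1, 5.31 and 9.336 for Tfap2e and 6.773 and 9.543 for Klf2. Differences were smaller for Abcc10 (-6.997 and -5.818), Pigt (9.24 and 9.958) and Lars2 (9.098 and 9.646). Spike-in means there were 4.46 and 4.997, so the larger differences exceed that in spike-in level. A further probe of Klf2 changed by log2 -0.07 for E14.5 against E13.5, where the listed probe changed by -3.39. For E15.5 against E14.5 these probes gave 0.27 and -0.42. Whether the 22 probes bind spike-in RNA was not tested.

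The same arrays paired crosswise over all genes. Deviations from the stage means correlated at r of -0.589 between E14.5 and E15.5 when arrays were matched by number, so that E14.5 array 1 resembled E15.5 array 2. A scale or brightness difference would vanish with quantile normalization, where r stayed at -0.575, and exchanged labels are argued against by the embryonic globins, whose lower E14.5 array exceeded the higher E15.5 array by at least 2.25 (log2), with within-stage spreads of 0.21 to 1.03. Of 13 cell type lists 0 were called by camera between the array pairs, against 1 at an unadjusted p under 0.05 and 0 with an estimated correlation. The same model called 0 single genes although the pattern runs over all genes, so uncalled lists cannot decide on a shift in cell types. List medians ran from -0.30 to 0.28. A difference in labelling between the array pairs may account for both this pattern and the spike-in levels; it was not tested, and neither was any biological explanation.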

How the results depend on the processing

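The normexp correction with extreme backgrounds replaced and the crossed pairing were chosen after seeing the data. Of 203 named changes, 186 were called. Quantile scaling kept 174 of these, median scaling 168, no filter 140, every probe 185, trended and robust variance 171, only the arrays compared 103, the random slide block 184, leaving out an array 113 to 146, normexp 45, and normexp with extreme backgrounds replaced 170. A call kept under the random slide block does not separate slide from stage in the comparisons that run across slides. All 186 kept their direction in the authors' table, which rests on the same arrays and is no independent check. Quantile and median scaling moved no total of genes or lists by over 1.5 times. By direction, median scaling gave 180 lower genes in place of 286 for E13.5 against E12.5, 818 lower in place of 1330 for E14.5 against E13.5 and 79 higher in place of 123 for E15.5 against E14.5, where quantile scaling gave 1 list down in place of 2. Signal over background limits the bounds: with probes above background on all arrays, E15.5 against E14.5 gave 22 genes (14 higher, 8 lower). Except where said, the cause was not tested.

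Counts below run in the order E13.5 against E12.5, E14.5 against E13.5, E15.5 against E14.5, E15.5 against E12.5 and any stage, against 876, 2746, 144, 7703 and 6829 genes and 11, 1, 5 and 13 lists. Normexp gave 2, 0, 0, 1244 and 572 genes (with 5680 and 331 at an unadjusted p under 0.05 where limma called 0), with 2 higher and 0 lower in the first and 642 higher and 602 lower for E15.5 against E12.5. It gave 16 lists (6 up and 10 down, in place of 6 and 5), 8 lists (7 up, 1 down) and 11 lists (4 up, 7 down) in the consecutive comparisons, with 3 background values on E13.5 array 2 over 10 times the median, up to 32329.5 against 60. Replacing these gave 551 genes (409 higher, 142 lower, 487 shared with the 876) and 16 lists (8 up, 8 down) for E13.5 against E12.5, 232 genes (199 higher, 33 lower, 75 shared with the 144) for E15.5 against E14.5, and 3 lists (2 up, 1 down) for E14.5 against E13.5. With them replaced, 33.2% of calls for E14.5 against E13.5 were higher (1308 higher, 2627 lower) in place of 51.6%, and 37.2% for E15.5 against E12.5 (3402 higher, 5744 lower) in place of 50.3%. No filter gave 419 genes (316 higher, 103 lower) and 884 genes (483 higher, 401 lower) in the 2 earlier comparisons, 108 (95 higher, 13 lower, 74 shared) for E15.5 against E14.5, and 2 lists (1 up, 1 down) and 8 lists (1 up, 7 down, in place of 3 up and 2 down) in the middle ones, the last without the calls of extracellular matrix and peritubular genes. For E15.5 against E14.5, trended and robust variance gave 25 genes (11 higher, 14 lower, 44% higher) in place of 123 higher and 21 lower, and slide as a block 226. Only the arrays compared, with fewer residual degrees of freedom, gave 139 (121 higher, 18 lower), 779 (428 higher, 351 lower) and 0 genes in the consecutive comparisons, the last with 2222 at an unadjusted p under 0.05. An adjusted p under 0.01 gave 221 (192 higher, 29 lower), 288 (160 higher, 128 lower), 0, 3761 (2120 higher, 1641 lower) and 2716 genes (the 0 with 2094 unadjusted). Camera with an estimated correlation gave 0 lists in each comparison (5, 0, 1 and 3 at an unadjusted p under 0.05), and fry gave 15 (7 up, 8 down), 3 (0 up, 3 down), 2 (1 up, 1 down) and 21 lists (12 up, 9 down). A random slide block (consensus correlation 0.0782) gave 2 lists for E14.5 against E13.5, both down, and 4 down in place of 2 for E15.5 against E14.5. Lists down in that comparison were 1 with slide as a block, with only the arrays compared and with probes above background on all arrays, which gave 3 down in place of 5 for E13.5 against E12.5. Slide as a fixed block could not be fitted for comparisons across slides or over all stages, and the authors' table, with 1 value per stage, gave no counts.

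With the replicate block, 544 (408 higher, 136 lower), 1611 (856 higher, 755 lower) and 89 genes (72 higher, 17 lower) were called in the consecutive comparisons. Deviations of same-numbered arrays correlated at 0.646 for E12.5 and E13.5, which share slides, at -0.589 for E14.5 and E15.5 and at -0.08 to 0.07 for other stages, so the number does not pair the arrays throughout. The crossed pairing gave 605 genes (512 higher, 93 lower) for E15.5 against E14.5.

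Leaving out an array gave 188 to 696, 219 to 2091, 0 to 78, 3492 to 7936 and 3594 to 6718 genes and 8 to 11, 1 to 2, 2 to 7 and 8 to 13 lists. With normexp the signs turned of Slco4c1 (0.53), Cdhr1 (0.19) and Tnc (0.089) for E13.5 against E12.5, and of Gsc (-0.25), Wnt3a (-0.72) and Dmc1 (-0.18) for E14.5 against E13.5. With extreme backgrounds replaced 0 of the named changes turned. For E15.5 against E12.5 signs turned of genes that were not called. Hba-a1 was at 0.76 with quantile scaling (adjusted p = 0.0216) and at -0.82 without E12.5 array 1 to 0.31 without E12.5 array 2. Sycp1 ran from -0.403 without E12.5 array 1 to 0.0894 without E12.5 array 2. The chosen probe of Sox9 ran from -0.551 without E12.5 array 2 to 0.0696 without E12.5 array 1, and was 0.0401 without E15.5 array 1.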

Other observations

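The tests on slide effects and on background were chosen only after the result was seen.

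Globin transcripts did not move as one group between E12.5 and E15.5. The embryonic genes Hbb-bh1, Hbb-y and Hba-x changed by log2 -7.24 ± 0.27, -6.77 ± 0.38 and -5.75 ± 0.24, whereas the adult gene Hbb-bt rose by 1.29 ± 0.21 and the adult gene Hba-a1 stood at -0.25 ± 0.44 (adjusted p = 0.679), and 0.76 under quantile scaling, where it was called. Hba-a1 was at 0.31 without E12.5 array 2. Both adult genes have near-identical copies that probes can fail to separate, and both were chosen after their values were seen. The cyclin-dependent kinase inhibitor list had a median of 0.12 and a mean of -0.20 for E14.5 against E13.5, and 1 rose, 4 fell and 9 were not called, and 2 were higher and 4 lower when adjusted over the list alone, with camera adjusted p = 0.968, and adjusted p = 0.976 with an estimated correlation. Cdkn2a changed by log2 -2.25 ± 0.44, Cdkn1b by -1.70 ± 0.39, Cdkn1c by -1.62 ± 0.25 and Cdkn1a, chosen after its values were seen, by -1.23 ± 0.19, whereas Cdkn2c rose by 1.53 ± 0.23. Cdkn2b had risen by log2 1.44 ± 0.23 from E12.5 to E13.5.

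Other members of lists that were not called also changed between E12.5 and E13.5. The imprinted gene Phlda2 rose by log2 2.23 ± 0.20, the heat shock genes Hspa1a and Hspb1 by 1.97 ± 0.24 and 1.24 ± 0.18, the inhibin subunit gene Inha by 1.69 ± 0.30 and the mesothelial gene Msln by 2.102 ± 0.23. Of the ovarian list, the oocyte transcription factor genes Figla and Nobox rose, Figla at least 4.27-fold and Nobox by log2 1.48 ± 0.28, while Lgr5 changed by -1.66 ± 0.18. Tubb3 rose by log2 1.53 ± 0.25, the matrix gene Dcn by 1.42 ± 0.23 and the retinoic acid-binding protein gene Crabp2 by 1.03 ± 0.18, and the oxygen sensor gene Egln3 changed by -1.08 ± 0.18. Tnc changed by log2 -1.12 ± 0.21 (-0.41 on another probe), but by 0.089 under normexp, and by -0.72 (adjusted p = 0.0798) with extreme backgrounds replaced. Over the whole span Phlda2 rose by log2 2.76 ± 0.20, whereas the imprinted genes Snrpn and Peg10 were lower, Snrpn at -1.73 ± 0.31 and Peg10 by at least 2.91-fold.

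More genes were called across slides than within a slide, 2746 for E14.5 against E13.5 against 876 and 144 for the comparisons within slides. If each probe's own response to the slide were the whole cause, probes of one gene would move independently, but over 587 called genes with a further probe their changes correlated at r = 0.613 and 78.7% had the same sign. Within slides these values were 0.872 and 94.6% for E13.5 against E12.5. For genes not called they were 0.298 and 64.8% across slides and 0.59 and 75.9% within, and the further probe of called genes changed by a median of 0.506 times the chosen one across slides and 0.926 times within. A probe's own response may thus account for part of the changes across slides. An effect of slide shared by all probes of a gene stays open. Slide 2 against slide 1 with stages held gave 1115 genes (167 higher, 948 lower). Slide 1 held array 1 and slide 2 array 2 of both stages, so there slide cannot be told apart from differences between the duplicates. For E14.5 against E13.5 an effect of slide cannot be told apart from the difference in stage, which may contribute as well.

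The 57 genes called higher at E15.5 and not above background at E14.5 had a median change of 2.63 and a lowest of 1.73. A background raised on all probes of the E15.5 arrays is argued against by the negative controls, whose means differed between an E15.5 and an E14.5 array by at most 5.18, with a standard deviation of up to 5.49. The unsubtracted signals of the 57 genes gained a median of 57.5 and a lowest of 17 from the higher E14.5 to the lower E15.5 array. That they gained follows in large part from how they were chosen. The local background at their spots changed by a median of -2 from E14.5 to E15.5, so for the median gene it did not rise with the signal. A background on single probes themselves was not tested and stays open. Ngp and Lcn2 among the called genes are granulocyte genes. So are Ltf and Stfa2l1, both chosen after their values were seen, which rose by log2 2.74 ± 0.18 and 2.04 ± 0.28; Ltf lost its call without E14.5 array 1, E14.5 array 2 or E15.5 array 2, and Stfa2l1 whichever of the 8 arrays was left out. RNA from neutrophils or other granulocytes may be a candidate source. Of 18 further granulocyte genes, listed before their changes were seen, 12 were measured, with a median of 1.01, quartiles of 0.15 and 1.58, 9 positive changes and 0 called by limma (camera p = 0.0319, and p = 0.144 with an estimated correlation). Camp, S100a9 and S100a8, abundant transcripts of neutrophils, stood at log2 2.95 ± 0.82, 1.85 ± 0.96 and 1.52 ± 0.81. The median of the 12 was 1.28 from E14.5 array 1 to E15.5 array 2 and 0.57 from E14.5 array 2 to E15.5 array 1. Unlike the 57 genes, all 12 were above background at E14.5, and 9 of them at E12.5 already, so this source stays open.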
